A study of Sus scrofa with 2 samples.

How the data were processed

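Per the labels' protocols, total RNA from the testes of 3 boars was pooled at each of 2 ages, 30 and 180 days, and about 18 to 30 nucleotides of small RNA were cut from a gel, ligated to adapters, amplified with 15 PCR cycles and sequenced on an Illumina 1G analyser. No molecular identifiers are named in the labels, so reads are not independent molecules and all intervals and floors cover counting error only. The authors deposited for each library a list of distinct tags matched to known miRNAs, with the raw read count of each tag, its sequence, and 1 miRNA name from any species; the counts were used as deposited, with no normalization. The aligner, the miRBase release and the genome build are not given in the sources used here. Other deposited columns hold the tag and miRNA lengths, the matching, mismatched (0 to 2) and unmatched bases, and an alignment score, which in every tag equalled 2 for each match minus 1 for each mismatch and 3 for each unmatched base; the score was not used further.

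The 30-day list held 7525725 reads and the 180-day list 852209, and perfect matches held 87.7% and 83.7% of them. The 1933 miRNA entries named in either list come from many species and were merged into 1311 miRNAs, here called by name and arm. Entries were merged when they had the same name and a sequence within 4 edits, or when they were identical over 17 or more bases with a shift of up to 3, but not when a species names them as separate paralogues. Entries left apart by these rules but given the same name and arm were then pooled, whatever their sequences. Names follow the lists, so a star marks the arm that was the rarer one when it was named. Each tag was compared with every entry (ungapped, up to 2 mismatches, 15 or more matching bases), and a tag that matched several miRNAs equally well was split equally between those with a mammalian entry; such tags held 1.42% of the 30-day and 1.46% of the 180-day reads. A tag whose given name was not among its best matches kept that name, so some tags of miR-99a sequence count as miR-100. Near-identical miRNAs, such as members of the let-7 family, can also exchange reads through sequencing errors. Entries of species other than mammals were kept under their names and can be chance matches.

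RPM were computed over all miRNA-matched reads of a library. The main comparison is the ratio of the 180-day to the 30-day value for the 436 miRNAs with 20 or more reads over both libraries, with the exact conditional (Clopper-Pearson) 95% interval of the count ratio. With 1 library per age there is no replicate check, no test across miRNAs and no p-value. A miRNA was called higher or lower when its ratio was 2 or more, or 0.5 or less, and the interval excluded 1. Where a library had 0 reads, the fold was bounded with 3 reads, which is a fixed floor and not the limit of the exact interval. Shares of reads have exact Clopper-Pearson 95% intervals.

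The measured members of 19 miRNA lists, fixed before the data were examined, were counted as higher, lower or neither, and the median log2 ratio of each list was placed among 10000 random lists of the same size matched on deciles of abundance, as a description of these libraries. The lists were germ cells of meiotic and later stages, undifferentiated germ cells and pluripotency, the let-7, miR-17-92, miR-15/16, miR-29, miR-30, miR-181 and miR-200 families, the DLK1-DIO3 region, miRNAs X-linked in human, Sertoli cells and gonadal soma, fibroblast and mesenchymal cells, endothelium, smooth muscle, striated muscle, red blood cells and platelets, white blood cells, and other organs. Both arms counted as members. Some miRNAs are in several lists, such as miR-16 in the red blood cell and the miR-15/16 lists, so the lists are not independent. The miRNAs named were the 10 most abundant of each library, the 10 highest and 10 lowest ratios among miRNAs with 100 or more reads and an interval excluding 1, up to 4 of the most abundant members of each list, and up to 5 precursors meeting the rule on arms (a difference of 20 percentage points or more, with 50 or more reads in each library). Other named miRNAs were chosen after their values were seen: miR-375, miR-184, miR-34a, miR-10b, miR-146a, miR-182 and miR-183 in the report, and those of the closing observations.

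Detection was counted at 3 or more reads, as deposited and after thinning the 30-day counts 100 times to the 180-day total. The leading 5′ end of a miRNA was the start with the highest mean share over both libraries, counted from its most read tag. Tag numbers were checked against read counts: in both lists the count never rose with the number, so the numbers were read as ranks over all tags of a library, and the tags missing between 2 listed ones were given a count between theirs. That reading is an inference from the numbers. Up to the last listed tag, it gave totals of 12711254 to 12876361 reads at 30 days and at least 12035098 at 180 days. At 180 days 7 tags ranked ahead of the first listed one and leave no upper limit. Tags ranked after the last listed one are not counted in either library, so the 30-day total has no upper limit either. Gene names around miRNAs come from the RefSeq annotation of Sscrofa11.1, which had a gene for 58 of the 76 named precursors; its coordinates are not used here.

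The interval and the size rule were tested on simulated counts for the 180-day against the 30-day library, with 200 miRNAs changed by known folds. The counts were drawn independently (Poisson), so they hold counting error only and no PCR duplicates, wrongly named tags or spread between pools. The results below are therefore not error rates of the calls on the real libraries. Of the 424 simulated miRNAs with enough reads, the interval covered the true ratio in 95.5%. The rule found 29 of 29 at a ratio of 4, 40 of 40 at 8, 24 of 29 at 0.25 and 33 of 38 at 0.125, and called 0 of 227 unchanged ones.

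Alternatives fixed before the data were examined were other scalings (median of ratios, TMM, the total without the 5 most abundant miRNAs), other treatment of tags that match several names, perfect matches only, tags of 20 to 24 nucleotides only, no tags of 1 read, both arms summed, other read minimums and other fold limits. Scaling to the whole-library totals, the single name given to each tag, and leaving out entries without a mammalian member were added after the data had been seen. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only.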

Results

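Small RNA was sequenced from whole testis of Junmu-1 boars, a white pig breed from China, at an age of 30 days, before sexual maturity, and at 180 days, after it. The RNA of 3 boars was pooled at each age and made into 1 library, so each age had 1 library and no replicate spread. The 30-day library held 7525725 reads in 82288 distinct sequence tags matched to known miRNAs, and the 180-day library held 852209 such reads in 28643 tags. Abundances are given as RPM, read counts scaled to the same total of miRNA-matched reads, and 3 reads corresponded to 0.399 RPM at 30 days and 3.52 RPM at 180 days. Ratios are those of the 180-day to the 30-day library with exact 95% intervals, which cover counting error only and compare these libraries, not the ages.

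The tags carried numbers that followed falling read counts over each library, so gaps in the numbering bounded the reads of tags outside the miRNA matches. Up to the last listed tag, the miRNA-matched reads made up 58.5 to 59.2% of the 30-day library and at most 7.08% of the 180-day library. Of the 10 most read tags, 10 were miRNA matches at 30 days and 1 at 180 days. Per read of the whole library, every log2 ratio below would therefore shift by -3.06 at the lowest totals of both libraries. The TMM scaling of edgeR shifted them by -0.94. Tags ranked after the last listed one are not counted, so neither total has an upper limit. Statements below per read of the whole library hold for the lowest totals. The ratios describe the makeup of the miRNA pool.

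**Figure D1:**
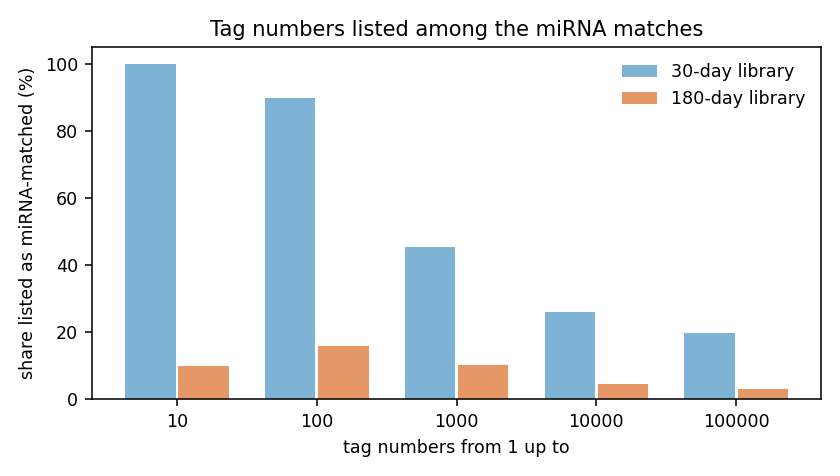
Share of tag numbers that were listed as miRNA matches (vertical axis, %), among tag numbers from 1 up to the value on the horizontal axis, for the 30-day and the 180-day library. Among the first 100 numbers, 90 were miRNA matches at 30 days and 16 at 180 days.

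Which miRNAs made up the testis pool before and after maturity was compared first. The 30-day pool was led by miR-199a-3p, a miRNA of mesenchymal cells, at 108835 RPM, followed by let-7a at 102755 RPM and let-7c at 93872 RPM. The 180-day pool was led by miR-202-5p, a gonadal miRNA, at 104917 RPM, followed by let-7a at 92734 RPM and the star arm of miR-140 (miR-140*, now called miR-140-3p) at 70570 RPM. The let-7 family, which is linked to differentiated cells, took 37.8% of miRNA reads at 30 days (exact binomial 95% interval 37.7 to 37.8%) and 29.5% at 180 days (29.4 to 29.6%). The miR-34a/b/c and miR-449 miRNAs together went from 0.00185% (0.00155 to 0.00218%) to 3.53% (3.49 to 3.57%).

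The remaining leaders at 30 days were miR-99a, miR-140*, let-7b, miR-202-5p, let-7f, miR-101 and let-7d, and those at 180 days were let-7f, miR-199a-3p, miR-99a, let-7c, let-7b, miR-101 and miR-29a. The 10 most abundant miRNAs took 72.2% of the 30-day reads (72.2 to 72.3%) and 61.3% of the 180-day reads (61.3 to 61.5%). Of these leaders, let-7c was 2.10-fold lower in the 180-day library (2.08 to 2.12) and miR-29a was 2.18-fold higher (2.16 to 2.21), although miR-29a was lower per read of the whole library. The leader miR-199a-3p, at 60206 RPM in the 180-day library, was 1.81-fold lower there (1.79 to 1.82), and miR-202-5p had a ratio of 1.77 (1.75 to 1.78), both under the 2-fold rule. The ratio of miR-140* was 0.987 (0.979 to 0.996) and that of let-7a was 0.902 (0.896 to 0.909).

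The ratio per miRNA addressed which miRNAs differed between immature and mature testis. The miR-34b/c and miR-449 miRNAs, which share a seed and are known from meiotic and postmeiotic male germ cells and from cells with motile cilia, were almost absent from the 30-day library and abundant in the 180-day library. miR-34c went from 45 reads (5.98 RPM) to 19287 reads (22632 RPM), a ratio of 3785 (2827 to 5191). miR-449a went from 2.46 to 7063 RPM, a ratio of 2873 (1827 to 4812). On the other side, miRNAs of the imprinted DLK1-DIO3 region were lower in the 180-day library, with miR-127 falling from 244 to 54.0 RPM, 4.53-fold (3.38 to 6.21). Over the 436 miRNAs with 20 or more reads, 134 were at least 2-fold higher at 180 days, 48 were at least 2-fold lower and 254 were neither. Among these 254, the interval lay wholly within 2-fold for 134, so the others cannot be called unchanged.

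The other miR-34b/c and miR-449 forms moved the same way as these, under each scaling tried, the whole-library one with the lowest totals, while their relative miR-34a had 43 and 4 reads and a ratio of 0.821 (0.214 to 2.26). miR-34b-5p had 2 reads at 30 days and 2269 at 180 days, a ratio of 10019 (2770 to 82777), and miR-34b-3p went from 1.59 to 1802 RPM, a ratio of 1130 (645 to 2192). The ratio was 913 (282 to 5525) for miR-449b and 814 (372 to 2227) for miR-34c-3p. The star arm miR-449b* had 157 reads at 180 days and 0 at 30 days, which makes it at least 462-fold higher against 3 reads. miR-9 and miR-9*, the arms of a miRNA best known from the nervous system, followed with ratios of 77.4 (43.5 to 150) and 72.5 (41.5 to 137). The remaining 1 of the 10 highest ratios was that of an entry known from a nematode, miR-1819, with 137 reads at 180 days and 0 at 30 days, at least 403-fold. Of its reads, 136 came from a single tag of 25 nucleotides with 2 mismatches and 3 unmatched bases, and no mammalian entry matched it.

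The lowest ratios were those of miRNAs with few reads left in the 180-day library. miR-485-3p went from 303 reads to 2, 17.2-fold lower (4.71 to 142), and miR-432 from 224 reads to 2, 12.7-fold lower (3.47 to 105.4). miR-204*, miR-196b and miR-149 were 9.51-fold (3.22 to 46.4), 7.64-fold (2.08 to 63.8) and 7.19-fold lower (1.95 to 60.0). miR-196a, whose genes lie among the HOX genes, had 126 reads at 30 days and 0 at 180 days, at least 4.76-fold lower. miR-487b was 5.47-fold (1.84 to 26.9), miR-542-5p 5.44-fold (1.82 to 26.7) and miR-708* 4.95-fold lower (2.74 to 9.99).

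The split between higher and lower miRNAs depended on the scaling and on read depth. With fewer reads at 180 days, a miRNA scarce at 30 days could hardly be called lower. With 100 or more reads over both libraries, 76 were higher and 41 lower. Per read of the whole library, with the lowest totals that the tag numbers allow, 24 miRNAs were at least 2-fold higher and 365 at least 2-fold lower. With TMM scaling these were 67 and 145, and with median-of-ratios scaling 104 and 81. The 24 included the 7 miR-34b/c and miR-449 forms above, miR-9, miR-9* and miR-375, and 8 of them were entries of species other than mammals.

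**Figure D2:**
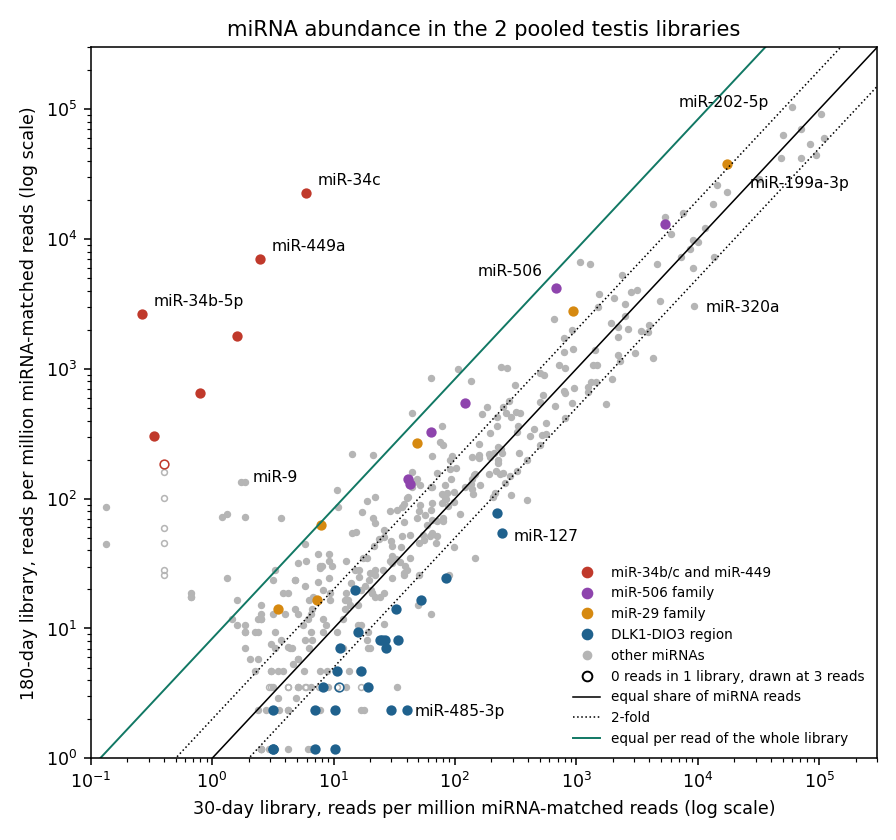
Abundance of the 436 miRNAs with 20 or more reads in the 30-day (horizontal axis) and the 180-day library (vertical axis), in RPM on log scales, 1 point per miRNA. miR-34c lies at 5.98 and 22632 RPM, far above the line of equal shares and above the line of equal reads per whole library, while the points of the DLK1-DIO3 region lie mostly below both and those of the miR-29 and miR-506 families mostly between them.

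Fixed lists of miRNAs were then compared with random lists of the same size and abundance. Germ cell miRNAs of meiotic and later stages were higher in the 180-day library, and miRNAs of the DLK1-DIO3 region were lower. Of the 13 measured members of the germ cell list, 10 were higher and 0 lower, with a median log2 ratio of 8.85, above all 10000 random lists. Of these members 7 were the related miR-34b/c and miR-449 forms, a dependence that random lists lack. The median was the value of miR-449b*, which was set by the floor of 3 reads at 30 days. The other higher members were miR-375 (ratio 60.8, 30.1 to 139), miR-122 (10.2, 8.22 to 12.7) and miR-184 (5.05, 3.16 to 7.93), the last of which was below 1 per read of the whole library. Its most abundant member in both libraries together, miR-191, had a ratio of 1.32 (1.30 to 1.34). Of the list of undifferentiated germ cells and pluripotency, 3 of 9 members were higher and 2 lower, with a median of -0.03 at percentile 25.6. The higher members were miR-146a, miR-182 and miR-183, with log2 ratios of 2.20, 3.38 and 4.27. Of these, miR-146a was lower per read of the whole library. miR-222 and miR-221, linked to undifferentiated spermatogonia, were 3.56-fold (3.34 to 3.79) and 2.28-fold lower (2.15 to 2.43), and miR-21 had a ratio of 0.983 (0.959 to 1.01). The star arm miR-221* had a ratio of 0.689 (0.614 to 0.771).

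The DLK1-DIO3 region carries a large cluster of miRNAs expressed from the maternal chromosome. Of its 27 measured members, 18 were lower in the 180-day library and 0 higher, with a median log2 ratio of -1.65 at percentile 0.00. miR-411 went from 224 to 77.5 RPM, 2.89-fold lower (2.26 to 3.75), miR-485-5p was 3.45-fold lower (2.24 to 5.61) and miR-379 was 3.19-fold lower (1.88 to 5.88). In the RefSeq annotation of Sscrofa11.1, the genes of miR-127 and miR-432 lie within RTL1, next to DLK1. The list of miRNAs that are X-linked in human had 13 of 45 members higher and 5 lower, with a median of 0.51 at percentile 67.7. Its higher members included miR-506 (ratio 6.22, 5.96 to 6.49) and miR-509-5p (2.41, 2.36 to 2.46), of a testis-expressed cluster, and both were lower per read of the whole library. As a share of miRNA reads, the miR-506 family took 0.633% at 30 days (0.628 to 0.639%) and 1.83% at 180 days (1.81 to 1.86%).

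Among the lists for somatic cells of the testis, the gonadal and Sertoli cell list had 4 of 13 members higher and 2 lower, with a median of -0.20 at percentile 4.31. Its member miR-320a was 3.07-fold lower (2.95 to 3.19), and miR-202-3p had a ratio of 0.654 (0.635 to 0.673) while the opposite arm, miR-202-5p, lay above 1. The fibroblast and mesenchymal list had 11 of 33 members higher and 1 lower, with a median of 0.16 at percentile 36.1. Its higher members were mostly miR-29, miR-143 and miR-145 forms, which also count in the miR-29 and smooth muscle lists. Of its most abundant members, miR-29a was higher, and miR-99a and miR-100 had ratios of 0.650 (0.644 to 0.656) and 1.79 (1.76 to 1.82). The most read tag named miR-100 was the leading miR-99a tag with a T added. The ratios of miR-99a and miR-100 are therefore not those of cleanly separated miRNAs. The smooth muscle list, miR-143 and miR-145 with their star arms, had 3 of 4 members higher, a median of 1.58 and percentile 94.5. miR-145 had a ratio of 3.72 (3.53 to 3.91), miR-145* of 3.25 (2.77 to 3.79), miR-143 of 2.76 (2.70 to 2.81) and miR-143* of 1.11 (1.01 to 1.23), all of them below 1 per read of the whole library. Neither of the endothelial miR-126 arms met the 2-fold rule: miR-126-5p had a ratio of 1.90 (1.69 to 2.13) and miR-126-3p of 1.30 (1.10 to 1.52), with a list median of 0.65 at percentile 63.0.

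The lists for other tissues and blood cells lay within the central 95% of random lists. In the striated muscle list 3 of 6 members were higher, with a median of 0.93 at percentile 80.3. miR-1 led it with a ratio of 4.90 (4.74 to 5.07), while miR-499-5p, miR-206 and miR-486-5p had ratios of 1.19 (1.09 to 1.30), 1.03 (0.831 to 1.26) and 0.698 (0.533 to 0.899). The red blood cell and platelet list had 4 of 8 members higher, with a median of 0.84 at percentile 80.1. miR-451, the main miRNA of red blood cells, had a ratio of 2.46 (2.36 to 2.56), miR-16 of 2.20 (2.13 to 2.27) and miR-15a of 1.46 (1.30 to 1.63). The white blood cell list had 2 of 8 members higher and 2 lower, with a median of 0.24 at percentile 33.6. miR-146b-5p had a ratio of 5.98 (5.42 to 6.59), and miR-142-5p, miR-342-3p and miR-150 had ratios of 1.14 (0.913 to 1.41), 1.22 (0.960 to 1.53) and 0.836 (0.599 to 1.14). Per read of the whole library, miR-1, miR-451, miR-16 and miR-146b-5p were below 1.

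The epithelial miR-200 family was scarce in both libraries, with 72.7 RPM summed at 30 days and 91.5 RPM at 180 days, and 0 of its 4 measured members met the 2-fold rule. The family's median was 0.39 at percentile 54.0. The ratio was 1.43 (0.984 to 2.03) for miR-200a, 1.20 (0.794 to 1.74) for miR-200b and 1.92 (0.864 to 3.86) for miR-200b*. miR-429 had 44 reads at 30 days and 0 at 180 days, which is at least 1.66-fold lower. The list for other organs had 6 of 13 members higher and 0 lower, with a median of 0.72 at percentile 77.0. It included miR-9 and miR-122 above and miR-192 (ratio 9.34, 8.47 to 10.3), while miR-128 and miR-7 had ratios of 1.17 (1.12 to 1.23) and 1.64 (1.44 to 1.87).

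Among the broadly expressed families, the miR-29 family had 6 of 6 members higher, with a median of 1.80 at percentile 95.9. miR-29b, miR-29c and miR-29c* had ratios of 5.43 (4.58 to 6.42), 2.96 (2.82 to 3.10) and 7.93 (5.37 to 11.7). Per read of the whole library miR-29b and miR-29c turned below 1, while miR-29c*, at 0.949, had a counting interval that included 1. The miR-30 family had 5 of 9 members higher (median 1.00, percentile 88.0), among them miR-30d with a ratio of 2.11 (2.07 to 2.15), miR-30e-5p with 2.19 (2.08 to 2.31) and miR-30c with 2.03 (1.82 to 2.25), beside 1.82 (1.78 to 1.86) for miR-30a-5p. The miR-15/16 family had 5 of 7 higher (median 1.14, percentile 93.0), with ratios of 2.20 (2.08 to 2.33) for miR-195, 2.43 (2.22 to 2.65) for miR-497 and 1.51 (1.40 to 1.62) for miR-15b. The called members of both families were likewise below 1 per read of the whole library.

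The let-7 family had 3 of 15 members higher and 1 lower, with a median of -0.07 at percentile 22.5. Its higher members were the rare star arms let-7a*, let-7b* and let-7d*, and no main arm was called higher. Its lower member was let-7c, while let-7f and let-7b had ratios of 1.27 (1.26 to 1.28) and 0.592 (0.586 to 0.599). The miR-17-92 cluster and its paralogues, linked to proliferating cells, had 1 of 20 members higher and 1 lower, with a median of 0.15 at percentile 19.8. miR-92a was 2.38-fold lower (2.21 to 2.57), and miR-25, miR-93 and miR-92b had ratios of 0.544 (0.519 to 0.570), 1.67 (1.55 to 1.81) and 0.599 (0.527 to 0.678). The miR-181 family had 0 of 7 members past the rule but a median of -0.78 at percentile 1.53, which moved inside the central 95% without tags of 1 read, with both arms summed and with a minimum of 100 reads. miR-181a, miR-181b, miR-181d and miR-181c had ratios of 0.5003 (0.469 to 0.534), 0.583 (0.536 to 0.632), 0.516 (0.448 to 0.591) and 1.06 (0.878 to 1.27).

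**Figure D3:**
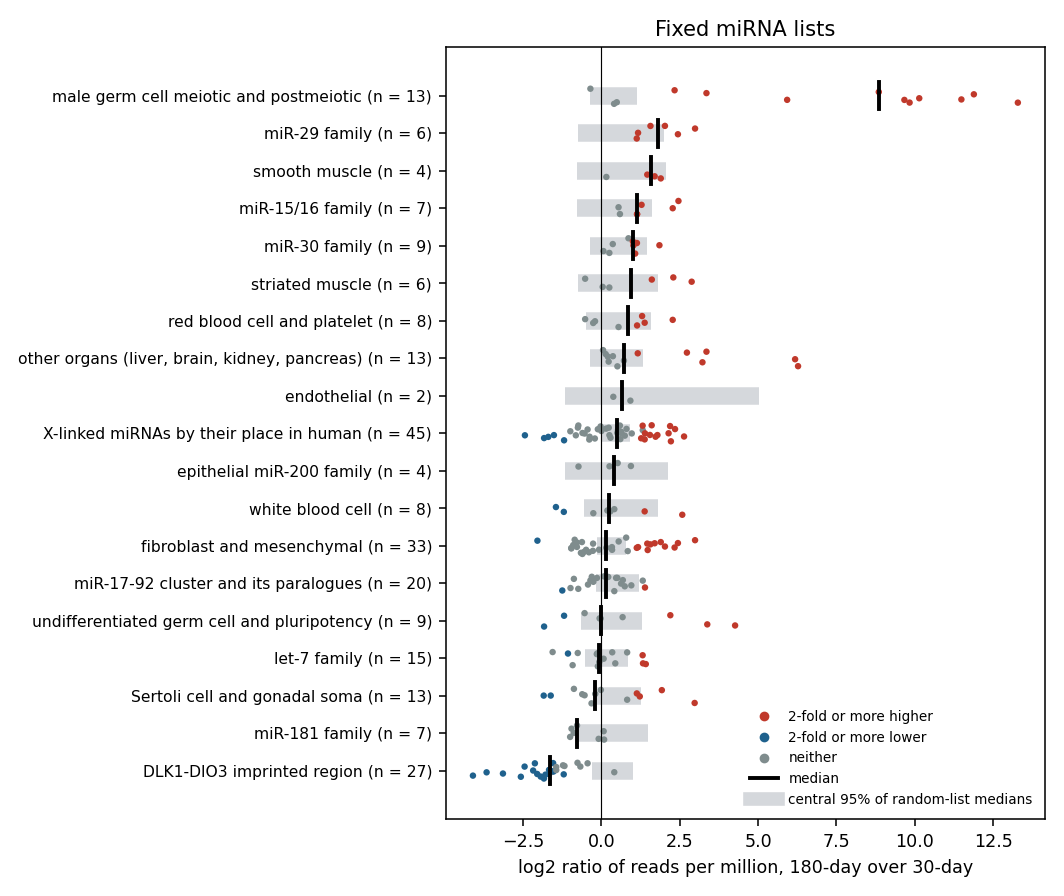
Log2 ratio of RPM between the 180-day and the 30-day library (horizontal axis) for the measured members of the 19 fixed lists, 1 point per miRNA form, with list medians as black bars and the central 95% of the medians of 10000 random lists as grey bands. The germ cell median of 8.85 lies right of its band, and those of the DLK1-DIO3 region (-1.65) and the miR-181 family (-0.78) lie left of theirs. Per read of the whole library all points shift left (log2 shift of -3.06 at the lowest library totals).

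Fewer miRNAs were detected in the 180-day library as deposited, and more once the totals of miRNA-matched reads were made equal. With 3 or more reads, entries without a mammalian member included, 669 miRNAs were detected in the 30-day library as deposited and 482 in the 180-day library, of which 414 were shared. After the 30-day counts had been thinned to 852209 reads, a mean of 388.6 were detected in it over 100 draws (SD 5.61, a spread of draws and not of animals). The whole libraries were not made equal, and mammalian entries were not counted apart. Part of the difference may therefore lie in entries that can be chance matches.

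The miRNA-matched tags had the length of mature miRNAs at both ages. Tags were listed by their match to miRNA entries, which favours this length, so it is no separate check of the libraries. Tags of 20 to 24 nucleotides held 97.2% of the reads at 30 days (97.2 to 97.2%) and 97.2% at 180 days (97.1 to 97.2%). The 22-nucleotide class fell from 49.7% (49.7 to 49.8%) to 44.7% (44.6 to 44.8%), and tags of 25 nucleotides and over went from 0.455% (0.450 to 0.459%) to 0.965% (0.944 to 0.986%). The leading 5′ end of the miRNA was carried by 90.3% of the reads at 30 days (90.2 to 90.3%) and 90.8% at 180 days (90.8 to 90.9%). Starts of single miRNAs differed more: for miR-140*, reads starting as ACCACAGGGTAGAACCACGGAC made up 49.8% at 30 days (49.6 to 49.9%) and 65.2% at 180 days (64.8 to 65.6%), most of the others starting a base earlier, as TACCACAGGGTAGAACCACGGAC. For miR-10b the leading start fell from 84.9% (84.7 to 85.2%) to 76.7% (75.8 to 77.6%), and for miR-34c it held 99.7% of 180-day reads (99.6 to 99.8%).

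**Figure D4:**
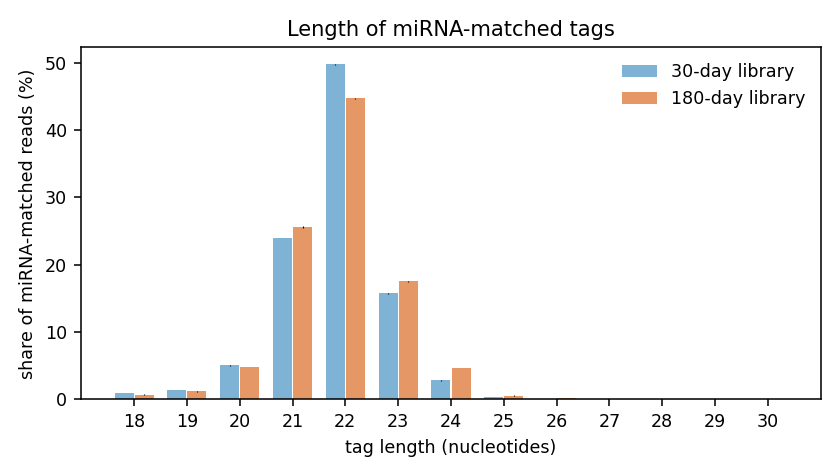
Share of miRNA-matched reads (vertical axis, %) by tag length in nucleotides (horizontal axis) in the 30-day and the 180-day library, with exact 95% binomial intervals as error bars. The 22-nucleotide class holds 49.7% and 44.7% of reads.

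The use of the 2 arms of a miRNA precursor was compared by a rule on percentage points. Of 115 precursors with both arms named and 50 or more reads in each library, 1 differed by 20 percentage points or more. In 76 of them 1 arm held over 95% of the 30-day reads, where the rule sees little: the main arm of let-7b went from 99.93% (99.92 to 99.94%) to 99.70% (99.64 to 99.75%). The precursor that met the rule was miR-132, a miRNA regulated by gonadotropin signalling in other gonadal cells, whose main arm took 77.1% of its reads at 30 days (72.4 to 81.4%) and 73 of its 146 reads at 180 days (41.6 to 58.4%). miR-132 itself had a ratio of 2.34 (1.78 to 3.03) and miR-132* of 7.86 (5.66 to 10.9). Per read of the whole library miR-132 was below 1, while miR-132*, at 0.94, had a counting interval that included 1.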

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

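The tests of this part were chosen after the results they bear on had been seen, and that on piRNAs was narrowed after a first run. The numbers of the tags, a column that the RPM ratios do not use, showed a signal of their own: tags outside the miRNA matches held at least 40.8% of the reads at 30 days and at least 92.9% at 180 days. Of tRNA fragments only those matched to 5 tRNA-derived entries (miR-1274a, miR-1274b, miR-720, miR-1308 and miR-1260) were counted, and other fragments stay open. Within the miRNA reads these entries went from 951.6 RPM to 1923 RPM. Per read of the whole library they were lower at 180 days, with a ratio of 0.242 (0.229 to 0.255) at the lowest totals. piRNAs, which are 26 nucleotides or longer, mostly start with T and are abundant in mature testis, may be among the added reads, but this cannot be told apart from other sources here, since distinct tags and reads give different answers. Of the distinct tags matched to entries of species other than mammals, 16.5% were 25 nucleotides or longer at 180 days (13.8 to 19.4%) against 9.39% at 30 days (8.08 to 10.8%), and of these long tags 69.0% (59.7 to 77.2%) against 58.3% (50.5 to 65.9%) started with T, where the intervals overlap; by reads, 27.1% (25.2 to 29.1%) against 4.52% (4.11 to 4.96%) were that long, and of these 80.7% (77.1 to 83.9%) against 32.7% (28.2 to 37.4%) started with T, with 136 of the 543 long reads at 180 days in a single tag. The sequences of the other tags are not analysed here, and the age of the boars stays open as an untested explanation.

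Reads that matched a plant miRNA entry perfectly over its full length numbered 183 at 30 days and 152 at 180 days, above the 3 reads that a count of 0 allows. Within the miRNA reads these are 24.3 RPM (20.9 to 28.1) and 178 RPM (151 to 209). The whole libraries held at least 12711254 and 12035098 reads. At these lowest totals the plant matches were not higher at 180 days per read of the whole library.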

How the results depend on the processing

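Read depth limits the miRNAs with few reads at 180 days, where 3 reads are 3.52 RPM, and leaving out replicates could not be done with 1 library per age. No paired analysis was possible because each age has 1 pooled library and no test was made. Whole-library totals, the single name per tag and mammalian entries only were chosen after seeing the data; the cause of each change was not tested beyond what a setting itself removes.
The number of miRNAs at least 2-fold higher (134) stayed between 94 and 163 in the settings other than TMM (67), whole-library totals (24), no read minimum (241), 100 reads (76) and a 4-fold limit (70). The number lower (48) stayed between 39 and 71 except with median of ratios (81), TMM (145), whole-library totals (365), a 1.5-fold limit (77) and a 4-fold limit (15). Lists outside the central 95% of random lists numbered 2 to 4 (3 in the main setting), but 5 with whole-library totals. The germ cell and DLK1-DIO3 lists stayed outside in every setting; the miR-181 family moved inside without tags of 1 read, with both arms summed and with 100 reads. The miR-29 family moved outside with perfect matches, tags of 20 to 24 nucleotides, no tags of 1 read, 100 reads, mammalian entries only and whole-library totals, the last of which also moved the smooth muscle list outside. A change of scaling adds the same amount to every log2 ratio, those of random lists included. Such settings could move a list only through the abundance deciles and are no separate check of the lists.
Among the miRNAs named by the fixed rule and called higher or lower, whole-library totals turned 20 log2 ratios below 0: miR-29a (-1.94), miR-29b (-0.62), miR-29c (-1.50), miR-29c* (-0.076), miR-509-5p (-1.79), miR-506 (-0.43), miR-143 (-1.60), miR-145 (-1.17), miR-145* (-1.36), miR-1 (-0.77), miR-16 (-1.93), miR-451 (-1.77), miR-146b-5p (-0.48), miR-195 (-1.93), miR-497 (-1.78), miR-30d (-1.99), miR-30e-5p (-1.93), miR-30c (-2.04), miR-132 (-1.84) and miR-132* (-0.089). For miR-29c* and miR-132* the counting interval included 0 at these totals, so their direction was not settled.
The share of the 10 most abundant miRNAs was 73.0% at 30 days and 62.1% at 180 days with unique tags, and 75.0% and 65.0% with perfect matches. By distinct tags, 83.0% and 84.9% were 20 to 24 nucleotides long and 77.1% and 78.9% had the leading 5′ end; without the most abundant miRNA these shares of reads were 97.0% and 97.7%, and 91.2% and 91.4%. With 1 read as the minimum, 1115 miRNAs were detected at 30 days, 852 at 180 days and 599.3 at 30 days after thinning. Precursors with a change of arm use numbered 1 with perfect matches too.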

Other observations

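The tests of this part, on scaling, the miR-200 family, low counts and somatic lists, were chosen after the results they bear on had been seen; those on scaling and somatic lists were changed after a first form with the same outcome, and that on the miR-200 family replaced a bound on the median log2 ratio, written before, which left the question open at 0.39. The miRNAs of this part were chosen after their values were seen. The miR-183 cluster, whose 3 genes lie between UBE2H and NRF1 in the RefSeq annotation of Sscrofa11.1, was higher in the 180-day library as a share of miRNA reads. The ratio was 10.4 (8.96 to 12.1) for miR-182, 19.2 (12.1 to 31.3) for miR-183 and 26.5 (9.15 to 93.2) for miR-96, the last on 5 and 15 reads. miR-383, whose gene lies within SGCZ, went from 63.9 to 846 RPM, a ratio of 13.2 (11.8 to 14.9), and miR-129-3p had a ratio of 15.5 (12.2 to 19.9). Other miRNAs of the miR-506 cluster were higher as well: the ratio was 5.09 (4.38 to 5.92) for miR-514, 4.57 (4.07 to 5.11) for miR-508, 4.11 (2.62 to 6.35) for miR-513a-5p, 3.45 (2.77 to 4.28) for miR-507 and 3.04 (2.43 to 3.79) for miR-510, all below 1 per read of the whole library.

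Opposite arms did not always move together. miR-151-3p had a ratio of 2.004 (1.92 to 2.09) and miR-151-5p of 0.738 (0.678 to 0.802), both below 1 per read of the whole library, so that the 5p arm took 39.0% of the reads at 30 days (38.3 to 39.7%) and 19.1% at 180 days (17.7 to 20.5%), a difference of -19.9 points, just under the limit of 20. Of the 51 entries with a ratio but no mammalian member, 24 were higher and 6 lower in the 180-day library. All tags matched only to entries without a mammalian member, those below the read minimum included, held 1241 RPM at 30 days and 2349 RPM at 180 days.

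The miR-34b/c and miR-449 forms had the highest ratios among the named miRNAs. Over the 7 measured forms and 3 other scalings (median of ratios, TMM and the total without the 5 most abundant miRNAs), the lowest lower interval bound of the ratio was 147.4. TMM took the number of higher miRNAs from 134 to 67. Each scaling multiplies all ratios by the same factor, so the bound follows from the size of these ratios and is no separate test. The rise of the 7 forms per read of the whole library was read at the lowest 180-day total, and that total has no upper limit. Ciliated epithelium of ducts in the 180-day tissue was examined through the miR-200 family, with 547 reads at 30 days and 78 at 180 days. That family did not rise with the 7 forms. It went from 72.7 to 91.5 RPM, with an upper interval bound of the ratio of 1.60, while the 7 forms went from 11.4 to 35295.9 RPM. That such epithelium would bring miR-200 miRNAs along was assumed and not tested, so this source stays open. The design contrasts the ages of 30 and 180 days. Maturation of germ cells between them is a possible explanation that was not tested, since each age is 1 pool.

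The median of the DLK1-DIO3 list lay at percentile 0.00 of random lists of equal abundance, so it was lower than lists with similarly few reads. This is the same percentile by which the list stood out, so it is no separate test of low counts. The list also holds opposite arms of the same precursors, which the random lists do not match. The lowest of the 4 somatic medians, that of the gonadal and Sertoli cell list, lay 1.45 above that of the DLK1-DIO3 list on the log2 scale. That list had 4 of 13 members higher and 2 lower, so its median says little about the share of a cell type. The 4 somatic medians ran from -0.20 to 1.58 and fell below 0 with the whole-library shift of -3.06. They cannot decide whether the share of somatic cells was lower. A lower share of somatic cells, a change within 1 somatic cell type, the age of the boars and a difference between the 2 pools stay open.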
